A study of Arabidopsis thaliana with 12 samples.

How the data were processed

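The series holds 1 table of probe values from 12 expression arrays hybridised with total RNA, 6 per group. The deposited values are signals on a linear scale that are never negative and reach at most 100. How the authors made these signals (background correction, scaling, the meaning of 100 and of 0) is not given in the sources used here. No date, slide or batch is given, so a batch that coincides with the group cannot be told apart from it. A total of 6 probes reached 100 in at least 1 sample, 1 of them with a single gene; their changes are bounded by that ceiling, and none of them is named.

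Probes were named through the platform annotation, with symbols updated by gene identifier from a RefSeq gene table of Arabidopsis thaliana, used for names only. Of the 3439 probes, 692 were listed with 1 gene, 870 with several and 1877 were not listed. A locus was matched for 690 probes, covering 689 loci. No gene was named from a probe with several genes, and unlisted probes are unnamed here, not without a gene. The locus with 2 probes, AT2G25870, gave changes of 1.20 and -0.42, and is not used in any list. Symbols of some list members are the usual names of their loci.

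Signals were analysed as log2(signal + 0.0415); the pseudocount is the 10th percentile of all positive signals. Sample medians differed by more than the 10% allowed by the rule fixed before the data were examined, so the 12 samples were quantile normalized (limma 3.58.1, R 4.3.3). Within both groups samples 1 and 2, 3 and 4, and 5 and 6 were each other's best match in their deviations from the group mean. The correlations were 0.29 to 0.44 in cold and -0.04 to 0.11 in recovery over all probes, and 0.73 to 0.85 and 0.32 to 0.48 over the brightest 25% of probes. The level of 0.5 fixed beforehand for averaging such pairs was thus not met over all probes. They were averaged all the same, before any count of changed genes had been seen, because the same numbers paired in both groups and independence could not be assumed. This departs from the fixed plan towards fewer samples, and the count with 12 independent samples is printed beside it.

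Recovery was compared with cold by limma (lmFit, eBayes with trend) over the 3 averaged samples per group, without covariates, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Of 28 gene lists fixed before the data were examined (433 entries), 23 entries were measured on a probe of their own, and 2 lists, photosystem II subunits and plastid ribosomal proteins, had the 3 members needed for a test. A further 15 lists were written from the names of the measured genes before any test and were adjusted separately. Lists were tested against the other probes with 1 gene by camera (correlation 0.01) and by camera with an estimated correlation. The rotation test fry asked whether the genes of a list moved, on balance, one way, without comparing them with other genes. The text names the 12 largest rises and 12 largest falls among probes with 1 gene that passed the test and whose mean in at least 1 group was above the lower quartile, up to 4 members of each fixed list tested, and, by a rule added later, the other measured members of the fixed lists and up to 3 members with the smallest p from 7 of the added lists; members of the other added lists, whose values had been seen, are given as counts. Other genes that the rule named were not analysed here. Where a locus had several probes, the brightest was taken.

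The procedure was tested on simulated data in which 200 of 3439 probes were changed. It recovered 94% of the changes of 2 on the log2 scale and 44% of those of 1, and called 9 of 3239 unchanged probes. The changed probes lay above the lower quartile of cold signal, as many up as down, and every recovery array was lowered by the same factor. In the real data 1399 of 3439 probes passed, and the balance of directions depended on the scaling. The simulated share of false calls therefore cannot be carried over to the real data. Alternatives covered the scaling between samples, the pseudocount, filters on dim probes, the variance model, array weights, a rank test, stricter thresholds, the treatment of pairs, the replicate number as a block, and each sample or pair left out. Alternatives chosen after seeing the data were the pairs left out, the scaling before the pseudocount, the background of the set test, and leaving out probes at 0 or near 100. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).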

Results

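Expression of 3439 probes was measured in total RNA of Arabidopsis thaliana Columbia wild-type plants, a laboratory strain of thale cress, from 2 conditions. The cold group had 24 h of medium light at 4 °C, which the labels describe as photoinhibitory, that is, light that damages photosystem II faster than it is repaired. The recovery group had the same treatment and then 24 h of medium light at 20 °C. Each group held 6 samples numbered 1 to 6, and samples 1 and 2, 3 and 4, and 5 and 6 of a group were each other's closest match, though over all probes below the level fixed beforehand for averaging, and clearly so in recovery. Each pair was averaged all the same, as the choice that counts fewer samples, so n is 3 per group. The labels do not say that samples came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

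The median deposited signal of a sample was 0.295 ± 0.0183 (SD, n = 3) in cold and 0.108 ± 0.0158 (SD, n = 3) in recovery. The brightest probe stood at 100 in 11 of the 12 samples. In each recovery sample 5 probes stood at 100, against 0 to 2 in each cold sample. Probes listed at 0 made up 5.89% ± 0.546 (SD, n = 3) of the table in cold and 13.2% ± 2.69 (SD, n = 3) in recovery. On the log2 scale the medians of the averaged samples differed by -1.23 between recovery and cold. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Changes in single genes are therefore given after quantile normalization, relative to the other probes of the same array, and not as absolute levels. A fold change is on the scale of log2(signal + pseudocount) and understates changes of dim genes. Its size also depends on the scaling between samples.

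**Figure D1:**
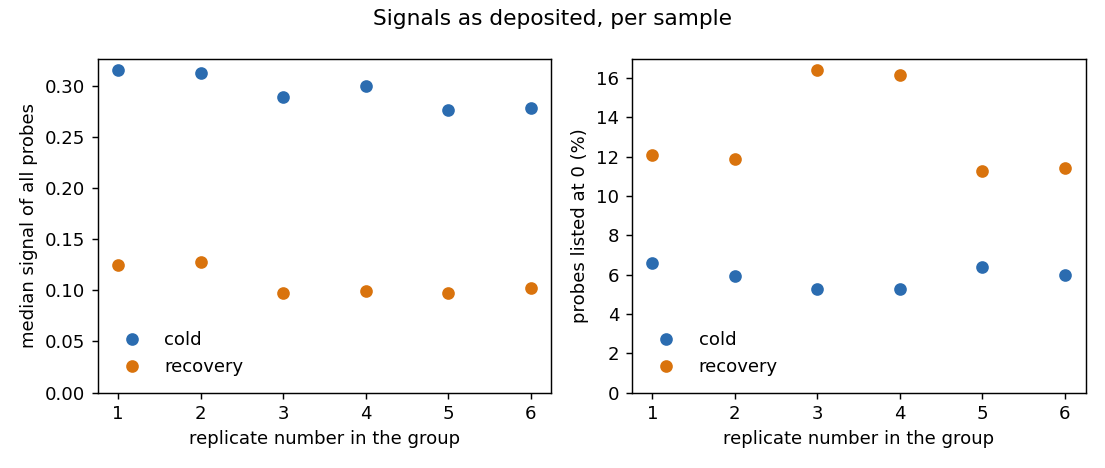
Median deposited signal (left) and percentage of probes listed at 0 (right) of each sample against its replicate number; points are single samples of the cold group (blue) and the recovery group (orange). Cold medians ran from 0.276 to 0.315 and recovery medians from 0.0971 to 0.128.

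The comparison of recovery with cold asks which transcripts differ between plants still in photoinhibitory cold and plants returned to 20 °C. Photosynthesis genes changed in both directions: of the 7 that were measured by a probe of their own, 5 rose and 2 fell in recovery, though PSBW, one of the latter, turned positive when samples were centred on their medians. PSAN, which encodes a lumenal subunit of photosystem I that helps plastocyanin dock, rose by 2.59 ± 0.17 on the log2 scale (SE, n = 3 per group), a 6.01-fold increase (adjusted p = 1.22e-06). LHCB1.5, a chlorophyll-binding antenna protein of photosystem II, rose by 1.44 ± 0.13 (adjusted p = 1.37e-05), and its deposited signal went from 7.63 ± 0.392 to 26.5 ± 3.03 (SD, n = 3). The size of its rise depended on the scaling: 1.55 with cyclic loess, 2.96 centred on medians and 3.24 with scaling before the pseudocount. PSBY, a small photosystem II subunit, rose by 1.44 ± 0.14 (adjusted p = 2.00e-05). PRK, the phosphoribulokinase of the Calvin cycle, rose by 1.44 ± 0.17 (adjusted p = 1.00e-04), and SBPASE, the sedoheptulose bisphosphatase of the same cycle, by 0.73 ± 0.18 (adjusted p = 0.0102). The rise of SBPASE is relative to the other probes: its deposited signal was 0.525 ± 0.109 in cold and 0.419 ± 0.0472 in recovery (SD, n = 3). PSB27, a lumenal factor in the assembly and repair of photosystem II, went the other way and fell by 1.89 ± 0.40 (adjusted p = 0.00396). In each of the 7 genes the 3 recovery values lay on 1 side of the 3 cold values, which chance gives in 10% of genes. However, 40.7% of all probes passed the test, and the share of all probes separated in this way was not counted. The separation therefore does not set these genes apart from other probes.

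The 7 genes as a pooled list, put together after the files were seen but before any test, had a median change of 1.44 and an adjusted p of 0.167 in the set test (0.851 with an estimated correlation). The list of photosystem II subunits, fixed beforehand, had 3 measured members, of which PSBY rose and PSB27 and PSBW fell; all 3 also passed when adjusted over the list alone. Its set test gave an adjusted p of 0.812 (0.850 with an estimated correlation). PSBW, a small photosystem II subunit close to the top of the signal range, fell by 0.56 ± 0.19 (adjusted p = 0.0377), a direction that turned to 1.08 when each sample was centred on its median. The fall of PSB27 missed the threshold (-0.84, adjusted p = 0.191) when samples were scaled to a common median before the pseudocount was added.

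Of the 6 measured genes for plastid ribosomal proteins, 4 rose and 2 did not pass the test, both over all probes and adjusted over the list alone. RPS6 (AT1G64510) rose by 2.45 ± 0.30 (SE, n = 3 per group; adjusted p = 1.22e-04) and RPS10 by 1.37 ± 0.24 (adjusted p = 0.00108), both proteins of the small subunit. The cold signal of RPS6 (0.0488 ± 0.0353, SD, n = 3) lay close to the pseudocount, and its change was 3.03 with the pseudocount halved and 1.86 with it doubled. RPL5 rose by 1.17 ± 0.20 (adjusted p = 0.00103) and RPL17 by 1.07 ± 0.18 (adjusted p = 8.30e-04), both of the large subunit. RPL29 was listed at 0 in 6 of 6 cold and 5 of 6 recovery samples and RPL34 in 3 of 6 cold and 6 of 6 recovery samples, so neither has a usable fold. The median change of the list was 1.12, and its set test passed with an adjusted p of 0.0106 (camera, 2 lists tested), but not with an estimated correlation, where the adjusted p was 0.0959. The rotation test for a shared direction (fry) gave an adjusted p of 5.43e-04. It does not compare the list with other genes, and it also passed for several added lists. Among them were photosynthesis (adjusted p = 0.00364), histone H3 (0.0158) and nucleotide synthesis (0.0370), whereas nuclear pore genes (0.801) and others missed it. A pass in fry thus does not set the ribosomal list apart. The sizes of the 4 rises are relative to the other probes. As deposited, where the median probe was at -0.86, changes were 1.45 for RPS6, 0.28 for RPS10, 0.11 for RPL17 and 0.070 for RPL5. The deposited signal of RPL5 was 0.305 ± 0.0698 in cold and 0.318 ± 0.0356 in recovery (SD, n = 3).

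**Figure D2:**
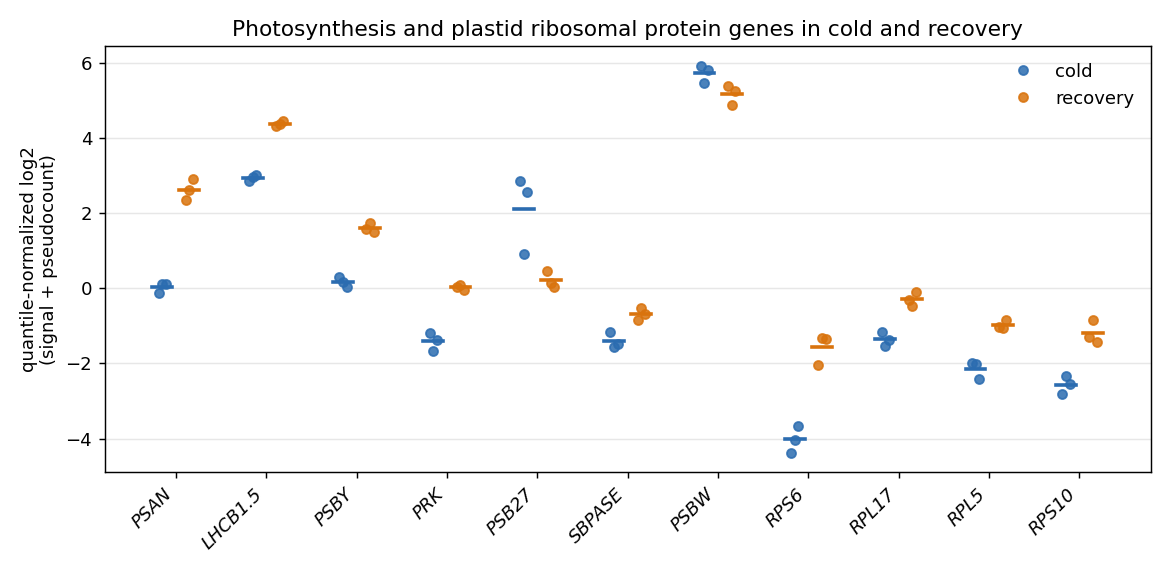
Quantile-normalized log2(signal + pseudocount) of 7 photosynthesis genes and 4 plastid ribosomal protein genes; each point is the average of a pair of samples (3 per group, cold in blue, recovery in orange) and bars are group means. PSAN, LHCB1.5, PSBY, PRK, SBPASE and the 4 ribosomal protein genes were higher in recovery, and PSB27 and PSBW lower. PSBW turned to higher when samples were centred on their medians. SBPASE was lower as deposited (-0.29), where the median probe was at -0.86.

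Other measured members of the fixed plastid lists also changed. XPT, the xylulose 5-phosphate translocator of the plastid envelope, fell by 1.83 ± 0.23 (SE, n = 3 per group; adjusted p = 1.36e-04). PRXIIE, a plastid peroxiredoxin that removes peroxides, fell by 1.42 ± 0.19 (adjusted p = 2.49e-04). CLPS1, an adaptor that brings substrates to the Clp protease of the plastid, rose by 1.33 ± 0.18 (adjusted p = 2.33e-04), and TIG, a trigger-factor-like chaperone, by 1.15 ± 0.24 (adjusted p = 0.00359). CHLM, the magnesium protoporphyrin methyltransferase of chlorophyll synthesis, rose by 1.42 ± 0.21 (adjusted p = 3.79e-04), and CHLP, the geranylgeranyl reductase that supplies the phytol tail of chlorophyll, by 0.42 ± 0.12 (adjusted p = 0.0180). The size of the CHLP change depended on the scaling: 0.17 as deposited, 0.31 with cyclic loess and 1.61 with scaling before the pseudocount. The changes of FATB (0.42 ± 0.28), NTRC (0.34 ± 0.22) and SPPA (0.12 ± 0.25) did not pass the test. The other fixed lists, among them cold-responsive, clock, senescence, root and epidermis genes, had no member on a probe of its own and were not analysed here.

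Among probes with 1 gene, the 12 largest falls after quantile normalization ran from -2.48 to -5.53. Their sizes depended on the scaling. AT4G35660 was at -5.54 with cyclic loess, -4.49 centred on medians and -4.27 with scaling before the pseudocount. AT2G46300 was at -3.23, -2.37 and -2.16 in the same order. AT4G35660 fell by 5.53 ± 0.14 (SE, n = 3 per group; adjusted p = 3.28e-09), with a deposited signal of 20.6 ± 4.46 in cold and 0.369 ± 0.0502 in recovery (SD, n = 3). AT4G18180, which encodes a pectin lyase-like protein, fell by 5.28 ± 0.17 (adjusted p = 2.74e-08). AT2G36480 fell by 4.47 ± 0.37, with 1 of 6 recovery samples listed at 0. HISN4 (AT4G26900), a plastid enzyme of histidine synthesis, fell by 4.16 ± 0.50 (adjusted p = 1.04e-04). It was listed at 0 in 2 of 6 recovery samples, both of 1 pair, and its 3 recovery values were -4.54, -2.37 and -2.33. Its change was -4.59 with the pseudocount halved and -3.67 with it doubled. AT5G39980 and AT1G31790 code for pentatricopeptide repeat proteins, a family that binds organelle RNA; the former fell by 3.33 ± 0.27 and the latter fell by 2.74 ± 0.33. AT3G18870, of the mTERF family of organelle nucleic acid-binding proteins, fell by 2.96 ± 0.18, and AT2G46300 fell by 3.06 ± 0.18. APTX, an aprataxin-like protein of DNA end repair, AT1G02020, AT2G39100 and AT5G11550 fell by 2.48 to 2.58; APTX was listed at 0 in 2 of 6 recovery samples. The recovery signals of APTX and AT5G11550 (0.0421 and 0.0428) lay close to the pseudocount, and their changes were -2.90 and -2.84 with it halved and -2.03 and -2.22 with it doubled. In all 12 genes each recovery value lay below each cold value, which their choice as the largest falls that passed makes likely by itself.

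After quantile normalization the 12 largest rises were led by AT4G31930, which rose by 3.26 ± 0.46 (SE, n = 3 per group; adjusted p = 3.04e-04), from a dim cold signal of 0.114 ± 0.139 to 0.582 ± 0.0670 (SD, n = 3). It was listed at 0 in 2 of 6 cold samples, its change was 3.82 with the pseudocount halved and 2.68 with it doubled, and PSAN (3.64) and CYN (3.56) exceeded it (3.55) with scaling before the pseudocount. PSAN came next, followed by CYN (AT3G23490), the cyanase that breaks down cyanate, which rose by 2.57 ± 0.16 (adjusted p = 1.22e-06). RPS6, described above, is also among the 12. AT1G44830, an ERF-type transcription factor gene, rose by 2.01 ± 0.16 (adjusted p = 5.19e-06), and AT1G62250, one of the brighter genes, by 1.90 ± 0.12, from a deposited signal of 2.91 ± 0.179 to 9.91 ± 0.127. AT3G09080 rose by 1.95 ± 0.14. AT1G50000 and AT1G21500 rose by 1.80 ± 0.25 and 1.75 ± 0.26; the former, with a cold signal of 0.0618, was at 2.27 with the pseudocount halved and 1.33 with it doubled. AT4G05030 and AILP1, an aluminium-induced protein gene, passed as higher, but their cold signals (0.0194 and 0.0149) lay below the pseudocount and were listed at 0 in 3 and 1 of 6 samples. Their changes moved from 2.96 to 1.63 and from 2.62 to 1.37 between the halved and the doubled pseudocount, so no fold is given. AT4G38490 passed as higher, but it was listed at 0 in 5 of 6 cold and 2 of 6 recovery samples, and 1 recovery sample held a signal of 2.23 while the other of its pair was listed at 0, so no fold is given.

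**Figure D3:**
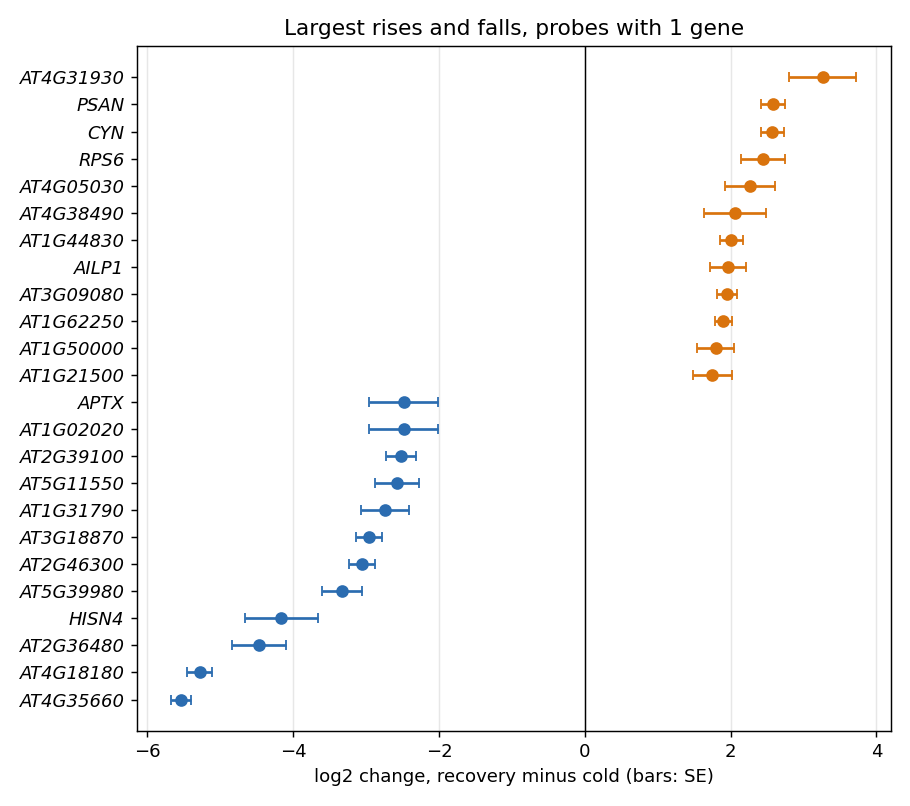
Log2 change from cold to recovery after quantile normalization (horizontal axis) of the 12 largest rises and the 12 largest falls among probes with 1 gene. Points are estimates from 3 averaged samples per group and bars are standard errors. Falls reached -5.53 (AT4G35660) and rises reached 3.26 (AT4G31930); the cold signals of AT4G38490, AT4G05030 and AILP1 lay below the pseudocount and those of RPS6 and AT1G50000, like the recovery signals of HISN4, AT5G11550 and APTX, close to it, so their points depend on it.

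Over the whole array 1399 of 3439 probes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 735 higher and 664 lower in recovery. Of the 690 probes with 1 known locus, 142 were higher and 132 lower. With all 12 samples taken as independent, 953 probes were higher and 811 lower. After quantile normalization, at least 2-fold changes numbered 366 higher and 441 lower, and at least 8-fold changes 4 higher and 43 lower. Changes of at least 8-fold were not counted under other scalings, and their sizes depended on the scaling. Scaled to a common median before the pseudocount, PSAN was at 3.64 on the log2 scale (2.59 after quantile normalization) and AT2G46300 at -2.16 (-3.06). The balance of directions depended on the scaling: 52.5% of the calls were higher in recovery after quantile normalization, against 46.9% (638 higher, 723 lower) with cyclic loess, 8.66% (192 higher, 2024 lower) for the values as deposited, where the median probe was at -0.86, 69.8% (1237 higher, 535 lower) with each sample centred on its median and 63.2% (888 higher, 518 lower) with samples scaled to a common median before the pseudocount.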

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

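Leaving out pairs, scaling before the pseudocount, changing the background of the set test and leaving out probes at 0 or near 100 were chosen after seeing the data. The 24 genes with the largest changes kept their direction under every alternative in which they were tested. Those listed at 0 in any sample, such as HISN4 and AT4G31930, were absent where probes at 0 were left out. Filters on dim probes also left out the dimmest of them. Calls were counted in the same way. Of their calls, 22 held under all but the exact rank-sum test, which cannot pass with 3 against 3 and called 0 probes (0 higher, 0 lower; 0 at an unadjusted p under 0.05, against 1706 with limma); AT1G21500 missed the threshold as deposited, and AT4G38490 with pairs as a random block (adjusted p = 0.179). As deposited, 2216 probes passed (192 higher, 2024 lower) and the median change over all probes was -0.86; it was 0.11 after quantile normalization, 0.31 with samples centred on their medians (1237 higher), 0.020 with cyclic loess, 0.051 without the dimmer 50% of probes, -0.069 with 0 as missing and 0.058 without probes at 0. As deposited, changes turned negative for SBPASE (-0.29), NDHN (-0.43), FBN6 (-0.37), FBN8 (-0.49), FBN2 (-0.65), AT3G46950 (-0.24), AT1G61990 (-0.54), TIG (-0.062), NTRC (-0.83), SPPA (-1.04), FATB (-0.75) and PIFI (-0.31). For 11 of these 12 the negative sign came from the shift of all probes, since they lay above the median probe as deposited; SPPA lay below it (-0.18). Changes as deposited and centred on medians differed by 1.17 for every named gene. Centring on medians turned PSBW (1.08), NDHS (0.25) and RPL34 (0.84) positive, and scaling before the pseudocount turned PSBW (1.36) and NDHS (0.53). Centred, NDHS still lay below the median probe (-0.056), while PSBW (0.77) and RPL34 (0.53) lay above it. RPL34 was listed at 0 in all 6 recovery samples. Why the places relative to the median probe differed between scalings was not tested. With scaling before the pseudocount the ribosomal protein list missed the threshold (adjusted p = 0.0888), so 0 of the 2 fixed lists passed. Among 5 scalings, with an estimated correlation that list passed only as deposited (adjusted p = 0.0463), and missed the threshold after quantile normalization (0.0959), centred (0.192), with cyclic loess (0.118) and scaled before the pseudocount (0.307). Stricter thresholds gave 874 probes (429 higher) at 0.01 and 807 (366 higher, 441 lower) at 2-fold, by construction. The count ran from 1089 to 1400 with a sample or pair left out. PSBW lost its call in several of these, for example without recovery samples 3 and 4 (adjusted p = 0.187). The replicate number pairs nothing detectable across groups (correlations of 0.06, 0.12 and -0.01), and with it as a block 1381 probes passed (708 higher, 673 lower). For the dimmest 25% of probes, signal near 0 limits what can be measured.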

Other observations

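The tests of scaling were chosen only after the changes had been seen; the other tests of explanations were set down before their results. Gene lists written from the names of measured genes add further groups, none of which passed the set test after quantile normalization with adjustment over 15 lists. The pooled photosynthesis list missed the threshold with cyclic loess too (adjusted p = 0.131). It passed as deposited (adjusted p = 1.73e-05), centred on medians (0.0302) and scaled before the pseudocount (0.00921), but under none of these with an estimated correlation (adjusted p = 0.235, 0.810 and 0.888). Of 18 pentatricopeptide repeat genes, 7 fell and 3 rose, with a median change of -0.29 (adjusted p = 0.216; 0.851 with an estimated correlation). Besides the 2 named among the largest falls, AT3G49740 fell by 1.23 ± 0.17 (SE, n = 3 per group). Of 6 mTERF genes, 3 rose, led by AT1G79220 (1.14 ± 0.19) and followed by AT3G46950 (0.90 ± 0.25) and AT1G61990 (0.64 ± 0.23); AT3G18870, which fell, was not in that list. Another list held 6 genes for subunits and assembly of the chloroplast NDH complex, which carries electrons around photosystem I. In it, NDHS fell by 0.97 ± 0.14 and NDHN rose by 0.76 ± 0.24. The direction of NDHS turned under scaling before the pseudocount (0.53), and PIFI, at 0.59 ± 0.26, did not pass. CRR21 and OTP85 of this list are also among the 18 pentatricopeptide repeat genes. In histidine and arginine synthesis, HISN4 and ASL, the argininosuccinate lyase, fell, ASL 2.65-fold, while DAPF of lysine synthesis passed as higher at signals close to the pseudocount (0.0401 in cold and 0.0435 in recovery); of 5 amino acid synthesis genes 2 fell and 1 rose.

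Of 5 antioxidant genes, PRXIIE and CCS, the copper chaperone of superoxide dismutase (-1.30 ± 0.26, SE, n = 3 per group; listed at 0 in 3 of 6 recovery samples, and between -1.71 and -0.92 with the pseudocount halved or doubled), fell, and GLDH, which makes the last step of ascorbate synthesis, rose by 1.22 ± 0.21. The call of CCS was lost without replicate 4 of both groups (-0.99, adjusted p = 0.0621). Of 4 tetrapyrrole genes, CHLM and CHLP rose and HEMA3, a glutamyl-tRNA reductase gene, fell by 0.68 ± 0.20. Of 5 fibrillins, plastid lipid-associated proteins, FBN6 (0.82 ± 0.25) and FBN8 (0.68 ± 0.23) rose relative to the other probes; FBN2 changed by 0.39 ± 0.18 without passing. In the remaining lists, 1 of 5 chaperones and foldases rose, 1 of 4 nucleotide synthesis genes rose and 2 of 3 histone H3 genes rose. Of these 2 histone genes, 1 was listed at 0 in 3 of 6 samples of each group. Its signals lay below the pseudocount (0.00634 in cold and 0.0126 in recovery). Of 4 nuclear pore genes 0 passed, 2 of 5 kinesins fell, and 1 of 4 GH9B endoglucanases rose and 1 fell. Among 6 flower and meristem regulators 1 rose and 1 fell.

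The number of changed genes was set against other groupings of the same 6 averaged samples. The real grouping gave 1399 probes, the highest of the other 9 groupings gave 0, and 1 of the 10 groupings gave as many as the real one, itself. With 10 groupings a share under 0.05 cannot be reached. Each of the other 9 groupings also mixed cold and recovery samples on both sides. The difference between cold and recovery then adds to the spread within each side and lowers the calls. The contrast of 1399 with 0 therefore says little by itself.

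Of the photosynthesis genes 5 of 7 rose in recovery and 2 fell, and of the plastid ribosomal protein genes 4 of 6 rose; 2 technical explanations for the raised medians of these lists were tested. If the normalization shifted genes of their brightness as a whole, random lists matched on mean signal would show the same median. The photosynthesis list lay at the 99.9th percentile of 10000 such lists (1.44 against a middle 95% of -0.97 to 0.75). The ribosomal list lay at the 100th (1.12 against -0.51 to 0.64). This argues against that explanation for the medians of the lists, not for each member. The mean change of the photosynthesis list, in which 2 of 7 genes fell, was lower (0.74) and was not set against random lists. The match was weaker for LHCB1.5 and PSBW, near the top of the signal range, where few brighter genes could be drawn. The random lists also ignored correlation between genes, and the photosynthesis list missed its set test (camera, adjusted p = 0.167). The ribosomal list passed that test (0.0106), but not with an estimated correlation (0.0959). If the choice of scaling made the raised medians, they would fall inside the matched lists under other scalings. Centring on medians, cyclic loess and scaling before the pseudocount were tried. The lowest percentile over all members was 99.1 for photosynthesis and 99.8 for the ribosomal list. By this measure the values argue against scaling as the whole cause of the raised medians, but not for single members. These random lists ignored correlation between genes too. In the set test the ribosomal list missed the threshold with scaling before the pseudocount (adjusted p = 0.0888), and the photosynthesis list with cyclic loess (0.131). With an estimated correlation both lists missed it under each of these scalings. With scaling before the pseudocount PSBW turned from -0.56 to 1.36, and PSB27 lost its call. A batch that coincides with the group stays open, and recovery from cold, as the design names it, remains a hypothesis.

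PSB27 fell while PSAN, PSBY and LHCB1.5 rose, and a hypothesis was that factors for the assembly and repair of photosystem II may be lower as a class once plants recover. Of 3 further such factors, 1 passed as lower: AT5G46390, a peptidase like the one that matures the D1 protein, fell by 1.12 ± 0.20 (SE, n = 3 per group; adjusted p = 0.00146). LPA19 rose by 0.63 ± 0.18 (adjusted p = 0.0181) and the rubredoxin AT1G54500 by 0.46 ± 0.16 (adjusted p = 0.0455). Both rises are relative to the other probes. Deposited signals went from 0.468 in cold to 0.330 in recovery for LPA19 and from 0.725 to 0.530 for AT1G54500. The change of the median probe as deposited was -0.86 on the log2 scale. With members going both ways relative to the other probes, the 3 genes do not decide the hypothesis. A fall of the class as a whole is not seen on that scale.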
